A study of Mus musculus with 23 samples.

How the data were processed

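Gene expression was measured by RNA sequencing in the cortex and the lumbar spinal cord of C57BL/6 mice aged 6 months. The mice were nontransgenic (NTg), carried a human C9orf72 transgene without the repeat expansion (F08), or carried one with the expansion (F112). The labels describe total RNA taken from frozen tissue with Trizol and a column kit. They name Ion Torrent protocols for brain and Illumina protocols for spinal cord, and a TruSeq kit without saying for which tissue. There were 23 libraries from 12 mice. The number of each mouse in the labels appears in both tissues, and 1 F112 mouse (6325) had a spinal cord library only. The labels do not give sex.

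The authors supplied 1 table per tissue with RPKM values (reads scaled to gene length and to the library's alignments) for each gene, 1 column per library. Each table also held the number of alignments of every library. The submitters' processing notes name TopHat2 version 2.0.8b, Partek and the builds mm9 and mm10. Which build or aligner served which table, how reads were assigned to genes, and whether libraries were stranded are not given in the sources used here. Read counts were not analysed here, so no count model was used. Alignments ranged from 9398450 to 14715900 per library in cortex and from 28479400 to 38811100 in spinal cord. At these depths the median standard error of a log2 difference between F112 and NTg was 0.16 in cortex and 0.056 in spinal cord.

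Gene names were used as the tables give them. Positions, gene types and GC content came from the GENCODE M21 annotation (GRCm38). Of 20863 names over both tables, 19636 matched a symbol there and 864 a synonym, while 38 fitted several genes and 363 matched none. Per table, 26 names had been turned into spreadsheet dates. These stayed in the tests and are not named. No symbol occurred more than once in a table, so summing entries of the same symbol had no effect.

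The values were used as scaled by the authors. Genes with a mean of at least 0.5 RPKM over the libraries of a tissue were kept, which left 13865 genes in cortex and 13839 in spinal cord. Log2 of RPKM plus a pseudocount of 0.5 was fitted with limma version 3.58.1 in R 4.3.3, using its empirical Bayes test with a mean-variance trend. The 3 genotypes of a tissue shared 1 fit, and each tissue was fitted apart. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All log2 fold changes are the first named group minus the other, with the standard error (SE) from the fit.

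The same fits were used to test gene lists with camera in limma, at a preset inter-gene correlation of 0.01 and an adjusted p under 0.05 over the lists of a comparison. Of 43 lists, 41 in cortex and 42 in spinal cord had at least 4 measured genes. The lists covered cell types of brain and cord, tissue that a dissection can include, stress and immune pathways, and genes tied to ALS and frontotemporal dementia (FTD). Each list was also tested with a correlation estimated from the data, and its genes were adjusted over the list alone. The comparisons, tests, lists and the first group of alternatives below were chosen before the data were examined.

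A difference between tissues was tested as the cortex difference minus the spinal cord difference over all 23 libraries, on 13078 genes kept in both tables. This fit was repeated with the animal as a replicate block. Exact two-sided permutation tests are given for single genes. They enumerate 35 or 70 rearrangements, allow no p below 0.0286, and were adjusted over the 6 comparisons of a gene. Apart from C9orf72, these genes were chosen for their limma values in the same data. The adjustment does not account for that choice.

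Genes were named by a rule. It took mouse C9orf72, up to 10 passing genes per direction with the largest change in a comparison, and, where fewer than 5 passed, all of them and the 5 genes with the smallest p in each direction. It added up to 4 members of each called list with the smallest p in its direction. A set of landmarks was taken in each comparison (Gfap, Aif1, Chat, Slc17a7, Snap25, Mbp, Tardbp, Sqstm1, Hspa5, Xist and Ddx3y). It also took up to 5 genes per tissue difference and up to 10 genes shared between comparisons, and no gene met this last part by passing in both F112 comparisons or in both tissues. Cpeb3, Rbbp6, Lrrc17, Rn45s, the genes named only as passing over a list alone and the genes gained under single alternatives fall outside the rule and were chosen after their values were seen. Some genes that the rule takes are not reported here, and they were left out of the outlier count.

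Alternatives chosen beforehand were median-of-ratios and quantile scaling, pseudocounts of 0.1 and 1, no filter and a filter at 5 RPKM, only the groups compared, robust empirical Bayes, array weights, Xist as a covariate, an estimated list correlation, the replicate block, and leaving out each library. Alternatives added after seeing the data were log2 alignments as a covariate, the same with Xist, Rn45s as a covariate, a correction of each library for its trend with GC content, and leaving out the 3 cortex libraries with Ttr above 100 RPKM. GC content was known for 98.7% of genes tested in cortex and 98.8% in spinal cord.

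The F112 against NTg fit was tested on simulated data with known changes and with noise drawn independently for each gene and library. In cortex (13865 genes) it recovered 36% of genes changed by 0.5 on the log2 scale, 80% at 1, 90% at 2 and 78% at -1, and called 12 unchanged genes. In spinal cord (13839 genes) it recovered 96%, 96%, 100% and 100%, and called 25 unchanged genes. For the tissue difference, 13061 genes were simulated, and only some of them were set to a difference of 1. Of the genes so set, 80% were recovered, and 6 unchanged genes were called. With the animal as a block, 62% of the genes so set were recovered, and 1 unchanged gene was called. Structure shared by the real libraries was not simulated, so these rates may not hold for them. Many more genes were changed at once than passed in any real comparison, which makes the adjusted threshold easier to pass. The rates therefore overstate what is recovered where few genes change. In real spinal cord, Fgfbp3 at 0.51 in F08 against NTg had a limma adjusted p of 0.284. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.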

Results

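The series compared the cortex and spinal cord of mice that carry human C9orf72, the gene whose intronic repeat expansion is a cause of ALS and FTD. Cortex libraries numbered 4 NTg, 4 F08 and 3 F112, and spinal cord libraries 4 of each. F112 against NTg asks about the expanded transgene, F08 against NTg about a transgene without the expansion, and F112 against F08 about the 2 lines. Each transgene was represented by 1 line, so an effect of the line and of the repeat cannot be separated.

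Alignments per library were 9810780 to 14257300 in cortex NTg, 9398450 to 14715900 in F08 and 9857850 to 13115500 in F112. Spinal cord libraries had 28479400 to 34100800 in NTg, 31459800 to 37367600 in F08 and 34097800 to 38811100 in F112. Across genes, Pearson's r between libraries of a group was 0.950 to 0.979 in cortex and 0.993 to 0.998 in spinal cord, and genes are not independent replicates. The first principal component held 38.2% of the variance in cortex and set the 5 libraries with the most alignments apart from the other 6. Xist, expressed from the inactive X chromosome, was at 23.6 to 36.5 RPKM in mice 6316, 6317, 6318, 6319, 6322 and 6323 and under 0.5 RPKM in the others. Each genotype had 2 such mice. Rn45s, the precursor of ribosomal RNA, ranged from 587 to 2640 RPKM in cortex. In spinal cord it was 459 RPKM in F112 mouse 6325 and 31.5 to 82.6 RPKM elsewhere.

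Mouse C9orf72 (3110043O21Rik, GRCm38 chromosome 4, 35191285 to 35226175) was the gene that set the genotypes apart in cortex. Its level there was 3.43 ± 0.55 RPKM in NTg (SD, n = 4), 6.62 ± 0.82 in F08 (n = 4) and 10.1 ± 0.56 in F112 (n = 3), with no overlap between groups. In spinal cord it was 12.0 ± 0.13, 11.8 ± 0.25 and 12.6 ± 0.64 RPKM (n = 4 each). In cortex the log2 fold change was 1.44 (SE 0.129, limma adjusted p = 0.00158) for F112 against NTg, 0.86 (adjusted p = 0.161) for F08 against NTg and 0.58 (adjusted p = 1) for F112 against F08. The exact permutation p was 0.0286 in all 3, the smallest possible, and 0.0571 adjusted over 6 comparisons. Spinal cord log2 fold changes were 0.07 (SE 0.038), -0.03 and 0.09, with limma adjusted p of 0.751, 1.00 and 0.445. Within cortex libraries of higher or lower depth the F112 difference was 1.45 and 1.47, and within those of high or low Xist it was 1.34 and 1.58. The values 1.45 and 1.58 rest on 1 F112 library, 6324. In F112 and F08 the depth and Xist classes held the same libraries, so they are not separate checks. The F08 difference within these classes was 0.72 to 1.00. The F112 call was kept in all 11 leave-outs. It ended when the 3 cortex libraries rich in Ttr were left out together, which left 2 NTg libraries (1.38, adjusted p = 0.0861). The F08 difference passed with median-of-ratios scaling (0.85, adjusted p = 0.0479) and with the GC correction (adjusted p = 0.0319), within a range of 0.0319 to 1.00 over the settings other than leave-outs. Whether reads of the human transgene were counted on the mouse gene is not given in the sources used here.

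**Figure D1:**
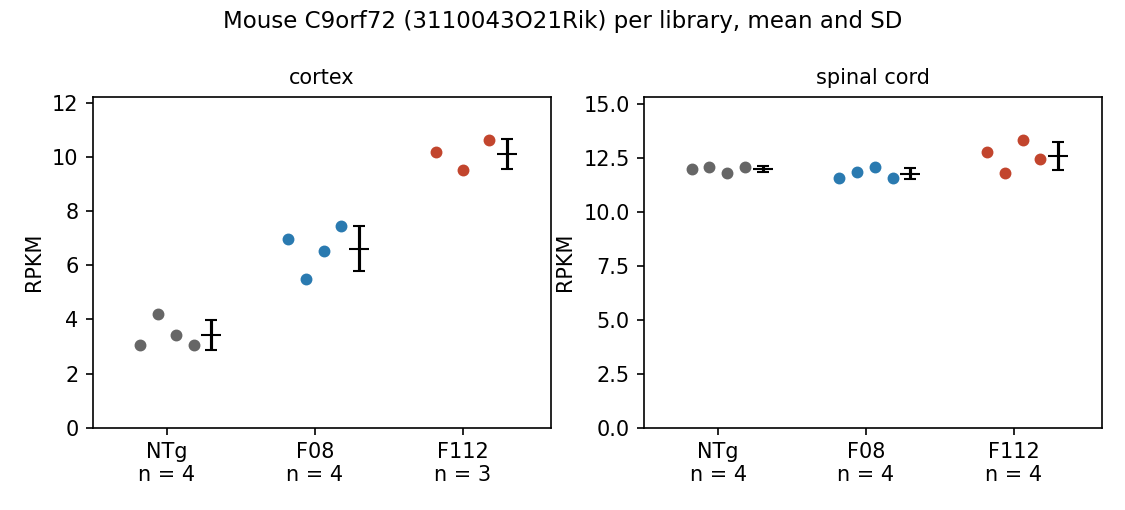
RPKM of mouse C9orf72 in each library of cortex and spinal cord by genotype, with the group mean and SD. In cortex the means were 3.43, 6.62 and 10.1 RPKM in NTg, F08 and F112, and in spinal cord 12.0, 11.8 and 12.6 RPKM.

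In the cortex of F112 mice against NTg, immediate early genes, which respond to neuronal activity, were lower as a group. Of 23 members 22 were below 0, with a median log2 fold change of -0.32 (camera adjusted p = 3.25e-05; adjusted p = 0.895 with an estimated correlation). Egr4 was 6.44 ± 0.50 RPKM in F112 (n = 3) and 8.95 ± 2.35 in NTg (n = 4), and Junb 24.6 ± 3.35 and 34.7 ± 11.1. Genes that respond to glucocorticoids fell as a group (10 of 16 below 0, median -0.19), as did circadian genes (13 of 18, median -0.12). Their adjusted p was 0.00909 and 0.0130, and adjusted p = 0.895 with an estimated correlation for both. Adjusted over the list alone, Sgk1 and Per1 were lower among the first and Per1 and Ciart among the second, while 0 members of either passed over all genes tested. Per1, a core clock repressor, was 17.9 ± 0.37 RPKM against 23.8 ± 3.75, and Ciart, another clock repressor, 6.82 ± 0.67 against 11.5 ± 1.24.

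Lists of cell types also moved in this comparison. Genes of choroid plexus and ependyma were lower (14 of 18 below 0, median -0.98, adjusted p = 4.08e-04). Ttr, a choroid plexus transcript, was at 705 and 375 RPKM in NTg mice 6322 and 6326 and 725 RPKM in F08 mouse 6320, and below 17 RPKM in each of the other 8 cortex libraries. Without these 3 libraries the choroid plexus median was -0.15 and the call ended (adjusted p = 0.734). Disease-associated microglia genes (18 of 21 below 0, median -0.21, adjusted p = 0.0120), blood genes (10 of 11, -0.47, 0.0130) and endothelial and pericyte genes (17 of 21, -0.11, 0.0298) were lower too. These 4 lists had adjusted p = 0.963 with an estimated correlation. Cd68, a lysosomal protein of microglia, was 4.16 ± 0.72 RPKM in F112 and 5.75 ± 1.12 in NTg. Replication-dependent histone genes were higher (14 of 23, median 0.11, adjusted p = 0.0277), with Hist1h2be at 3.51 ± 0.46 and 2.77 ± 1.05 RPKM. The C9orf72 region list was called as higher (adjusted p = 0.0327) with a median of 0.06, and C9orf72 was its 1 member past the threshold. Both had adjusted p = 0.895 with an estimated correlation.

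By limma, 1 gene of 13865 passed in this comparison, mouse C9orf72, and 273 had an unadjusted p under 0.05 where 693 were expected by chance. Of the other named genes, Cryga (log2 fold change 0.80, SE 0.181), Magee2 (0.66), Rtca (0.31) and Gabrb1 (0.42) were the next by p above 0. Below 0 they were Ciart (-0.71), Tmem107 (-0.85), Scx (-0.88), Lrrc25 (-0.90) and Fam161a (-0.64). The glucocorticoid list was called in all 11 leave-outs, with medians from -0.32 (without NTg 6326) to -0.10 (without NTg 6323). Immediate early genes were not called without F112 6324 (adjusted p = 0.332; medians -0.48 to -0.17 over leave-outs), and choroid plexus genes were not without NTg 6322 (0.343; -1.30 to -0.61). The other 6 called lists lost their calls in 3 or 4 leave-outs each, and C9orf72 region did so without NTg 6326, NTg 6327, F08 6320 or F112 6324. Their medians ranged from -0.41 to -0.06 (disease-associated microglia), -0.74 to -0.13 (blood), -0.17 to 0.00 (endothelial), -0.18 to -0.03 (circadian), 0.02 to 0.30 (histone) and -0.02 to 0.16 (C9orf72 region). Without F112 6317 the histone test turned to lower (median 0.02, adjusted p = 0.987). The histone and C9orf72 region calls also ended with median-of-ratios scaling (adjusted p = 0.0761 and 0.0557) and the GC correction (0.0762 and 0.0881), and with quantile normalization the region median was 0.10. Without the Ttr-rich libraries the circadian (adjusted p = 0.253) and C9orf72 region calls ended (0.0522, median -0.07), while medians grew for disease-associated microglia (-0.51), blood (-1.08), endothelial (-0.20), immediate early (-0.50), glucocorticoid (-0.38) and histone genes (0.20). In place of 9 lists, 3 were called without NTg 6327, 16 without NTg 6322, 18 without F112 6324 and 19 without the 3 Ttr-rich libraries; without F112 6317, 2 genes passed (with Snora52).

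In the cortex of F08 mice against NTg, genes of myelin and its oligodendrocytes were higher as a group. All 20 members were above 0, with a median log2 fold change of 0.42 (camera adjusted p = 1.75e-15; adjusted p = 0.898 with an estimated correlation). Cldn11, a tight junction protein of myelin, was 52.5 ± 5.84 RPKM in F08 and 36.7 ± 9.50 in NTg (SD, n = 4 each). NTg mouse 6322 had 401 RPKM of Mbp, a main myelin protein, against 783 to 808 in the other NTg mice. The list stayed called without any 1 library, with a median of 0.21 without that mouse, and without the 3 Ttr-rich libraries, mouse 6322 among them, its median was 0.13 (adjusted p = 1.33e-05). Oligodendrocyte precursor genes were higher too (11 of 14 above 0, median 0.17, adjusted p = 0.00371), but not called without the Ttr-rich libraries (median 0.04, adjusted p = 0.0753). Sox10, a transcription factor of this lineage, passed adjusted over the list alone at 13.5 ± 1.00 and 9.08 ± 1.81 RPKM. Ribosomal protein genes (67 of 84 above 0, median 0.10, adjusted p = 7.36e-06), hippocampus and thalamus genes (13 of 16, 0.35, 0.00426) and oxidative phosphorylation genes (41 of 51, 0.05, 0.0315) were also higher. Lower lists were striatum (20 of 20 below 0, median -0.52, adjusted p = 0.00361), immediate early (16 of 23, -0.22, 0.0138) and choroid plexus and ependyma (14 of 18, -0.48, 0.0232). Each of these lists had adjusted p = 0.898 with an estimated correlation.

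Among region markers, Calb2, a calcium-binding protein, was 30.1 ± 4.32 RPKM in F08 and 14.7 ± 17.0 in NTg cortex. The striatum call was lost without NTg 6326 (adjusted p = 0.651), F08 6319 (0.266) or F08 6320 (0.667), and oxidative phosphorylation turned to a median of -0.04 without NTg 6322. The precursor call ended without NTg 6327 (adjusted p = 0.0604), the hippocampus call without F08 6318 (0.201), and the oxidative phosphorylation, immediate early and choroid plexus calls in 4, 4 and 5 leave-outs. Medians over leave-outs ranged from -1.11 to -0.15 (striatum), 0.08 to 0.25 (precursor), 0.21 to 0.60 (hippocampus), -0.33 to -0.04 (immediate early), -0.84 to -0.16 (choroid plexus) and 0.02 to 0.16 (ribosomal). In place of 8 lists, 4 were called without F08 6318 and 14 without F08 6320. Without the Ttr-rich libraries the median of all genes was itself -0.07, against -0.0016 in the main fit. In that setting the ribosomal protein median was -0.08 (camera adjusted p = 0.998) and that of oxidative phosphorylation -0.09 (0.419). Both lie near the median of all genes, and the ribosomal test direction stayed higher. The hippocampus (median 0.11, adjusted p = 0.165), striatum (-0.50, 0.616) and choroid plexus calls (-0.41, 0.583) ended there too. The choroid plexus call ended with quantile normalization (adjusted p = 0.0716), and that of oxidative phosphorylation with median-of-ratios scaling (0.0591) and the GC correction (0.0503).

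By limma, 0 genes passed in cortex F08 against NTg, and 362 of 13865 had an unadjusted p under 0.05. After C9orf72 the smallest p among higher genes belonged to Ide, the insulin-degrading enzyme, at 9.21 ± 2.00 RPKM in F08 and 5.47 ± 0.75 in NTg (log2 fold change 0.69, SE 0.145, adjusted p = 1.00). For Ide the exact permutation p was 0.0286, the smallest possible, and 0.0429 adjusted over 6 comparisons, which does not account for its choice from all genes tested. Then came Nrip3 (0.74), Pstpip2 (0.65) and Sox10 (0.57), and in the other direction Ciart (-0.59), N6amt1 (-0.51), Sgk1 (-0.59) and F3 (-0.35). Mir8094 was listed at 0 in all 4 F08 libraries and at 1.70 ± 1.26 RPKM in NTg. With the Ttr-rich libraries left out, 3 genes passed as lower (Mir677, Cox6a2 and Gm14850).

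Between the lines in cortex, myelin genes were lower in F112 than in F08. All 20 members were below 0, with a median log2 fold change of -0.47 (camera adjusted p = 5.82e-14; adjusted p = 0.966 with an estimated correlation). Mag, a myelin adhesion protein, was 43.0 ± 8.25 RPKM in F112 (n = 3) and 62.9 ± 8.79 in F08 (n = 4), and Myrf, a regulator of myelin genes, 5.09 ± 1.16 and 7.71 ± 1.61. Against NTg the same list in F112 had a median of -0.06 and did not pass (adjusted p = 0.941). Ribosomal protein genes (74 of 84 below 0, median -0.12, adjusted p = 2.57e-04) and unfolded protein response genes (21 of 24, -0.12, 0.0297) fell as lists, each with adjusted p = 0.966 with an estimated correlation. Hspa5, an endoplasmic reticulum chaperone, was 56.7 ± 13.2 and 67.1 ± 4.61 RPKM. In place of 3 lists, 9 were called without F08 6319, 6 without F08 6318, and 5 without F112 6316 or F112 6317. The myelin call held in all 11 leave-outs, with medians from -0.61 to -0.31 (without F112 6317). The ribosomal call ended without F112 6324 (adjusted p = 0.581), and the unfolded protein call ended without F08 6320 (0.074), F08 6321 (0.0725), F112 6316 (0.254) or F112 6317 (0.117), with medians of -0.21 to -0.07 over leave-outs and -0.07 without the Ttr-rich libraries. By limma, 0 genes passed and 342 had an unadjusted p under 0.05; without F112 6317, 1 gene passed (Snora52). Ide was lower by -0.80 (SE 0.156, adjusted p = 1, exact permutation p = 0.0286, the smallest possible). Pfkfb3, a glycolytic regulator, had -0.48, Tmem128 -0.35 and Scx -0.87, while Cryga had 0.67, 2900055J20Rik 0.60 and Gm7120 0.60. Snora33 was listed at 0 in the 3 F112 libraries and at 1.44 ± 0.59 RPKM in F08.

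In the spinal cord of F112 mice against NTg, immediate early genes were again lower as a group. All 20 measured members were below 0, with a median log2 fold change of -0.15 (camera adjusted p = 2.89e-08; adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone 7 passed (Fos, Junb, Nr4a1, Ier2, Dusp1, Klf2 and Sik1), and 0 over all genes tested. Dusp1, a phosphatase that shuts off MAP kinases, was 5.81 ± 0.77 RPKM in F112 and 7.30 ± 0.27 in NTg (SD, n = 4 each), and Junb 3.14 ± 0.48 and 4.12 ± 0.36. The list of motor neuron genes was higher (11 of 15 above 0, median 0.09, adjusted p = 5.13e-04; adjusted p = 0.563 with an estimated correlation), and both lists kept their calls in all 12 leave-outs, with motor neuron medians of 0.05 (without F112 6317) to 0.13. Dorsal root ganglion genes, a list that shares Calca, did not pass and went the same way (4 of 6 above 0, median 0.08, adjusted p = 0.0552). Adjusted over the list alone the 4 higher motor neuron genes were Slc5a7, the choline transporter, Chodl, and Calca and Calcb, which encode CGRP peptides that sensory neurons also make. Calca was 33.4 ± 7.00 against 22.7 ± 4.38 RPKM, and Chat, the enzyme that makes acetylcholine, 10.9 ± 0.44 against 10.8 ± 0.98.

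Heat shock genes (16 of 20 above 0, median 0.07, adjusted p = 5.86e-05; adjusted p = 0.563 with an estimated correlation) and unfolded protein response genes (20 of 24, 0.06, 0.00352; adjusted p = 0.598 with an estimated correlation) were higher. Both calls rested on F112 mouse 6325, the library high in Rn45s: without it the medians were 0.00 and adjusted p = 0.788 and 0.757. Hsp90aa1, a cytosolic chaperone, was 379 ± 16.0 and 353 ± 9.57 RPKM. Interferon response genes were higher by a median of 0.04 (17 of 23, adjusted p = 0.00447), with Ifit3 at 6.44 ± 0.62 and 5.42 ± 0.58 RPKM. Lower lists were histones (12 of 13 below 0, median -0.23, adjusted p = 0.00527), blood (7 of 7, -0.50, 0.00598) and astrocyte (15 of 17, -0.05, 0.0157). With an estimated correlation adjusted p = 0.607 for blood and adjusted p = 0.563 for interferon, histone and astrocyte genes. The interferon, histone and astrocyte calls were each lost in 2 leave-outs and the blood call in 4, with medians of 0.03 to 0.07 (interferon), -0.34 to -0.08 (histone) and -0.70 to -0.26 (blood). The astrocyte call also ended with quantile normalization (median -0.02, adjusted p = 0.174), where the interferon median was 0.06. Gfap, the astrocyte filament, was 428 ± 20.9 and 440 ± 26.2 RPKM.

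The 1 gene of 13839 that passed by limma in this comparison was 4930413G21Rik, and 984 had an unadjusted p under 0.05 where 692 were expected. It was 0.93 ± 0.19 RPKM in F112 and 2.00 ± 0.42 in NTg (log2 fold change -0.80, SE 0.111, adjusted p = 0.0434; lower in 4 of 4 libraries). Its exact permutation p was 0.0286, the smallest possible, and 0.0857 adjusted over 6 comparisons, which does not account for its choice from all genes tested. Within mice of high and low Xist the difference was -0.84 and -0.77. The annotation places it at chromosome 7, 122969058 to 122970050, on the minus strand inside Rbbp6 (122965686 to 123002557, plus strand), a gene of an E3 ubiquitin ligase whose log2 fold change was 0.03 (SE 0.048). Its call was lost in 11 of 12 leave-outs, among them all those of NTg (6322, 6323, 6326 and 6327) and F08 (6318 to 6321) mice and of F112 6317, 6324 and 6325, with log2 fold changes of -0.85 to -0.69 and adjusted p up to 0.159. It also ended with pseudocount 1, no filter, only the compared groups, array weights, log2 alignments or Rn45s (adjusted p = 0.0504 to 0.578). Without F112 6316, 2 genes passed (with Ppp1r35). Others with small p were Ppp1r35 (-0.52), the hemoglobin gene Hbq1a (-0.79), Gtl3 (-0.23) and Hapln2 (-0.24), and Pou3f3os (0.22), Cd24a (0.25), Rpl22l1 (0.16) and Calcb (0.38).

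In the spinal cord of F08 mice against NTg, Ide rose to 15.7 ± 1.76 RPKM from 9.64 ± 0.51 (SD, n = 4 each). Its log2 fold change was 0.67 (SE 0.067, limma adjusted p = 7.56e-04), with all 4 F08 libraries above every NTg library. Ide lies on chromosome 19 (37268743 to 37337852), and near it Btaf1 (36926079 to 37012752), a regulator of TATA-binding protein, was 4.99 ± 0.55 against 3.53 ± 0.16 RPKM (0.44, adjusted p = 0.0639). Fgfbp3 (36917550 to 36919615), an FGF-binding protein, was 2.13 ± 0.33 against 1.35 ± 0.12 RPKM (0.51, adjusted p = 0.284). Cpeb3, between Btaf1 and Ide, was 14.5 ± 0.10 against 14.4 ± 0.49 RPKM (log2 fold change 0.01, SE 0.040). Exact permutation p was 0.0286 for Ide, Btaf1 and Fgfbp3, the smallest possible, and adjusted over 6 comparisons 0.0429, 0.0857 and 0.0857. That adjustment does not account for their choice from all genes tested. Within mice of high and low Xist the Ide difference was 0.63 and 0.71. By limma 1 gene of 13839 passed, and 567 had an unadjusted p under 0.05. The Ide call was kept in all 12 leave-outs and lost with log2 alignments as a covariate (0.60, adjusted p = 0.0731; 5.97e-05 to 0.0731 over the settings other than leave-outs). In this tissue each F08 library had more alignments than 3 of the 4 NTg libraries.

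**Figure D2:**
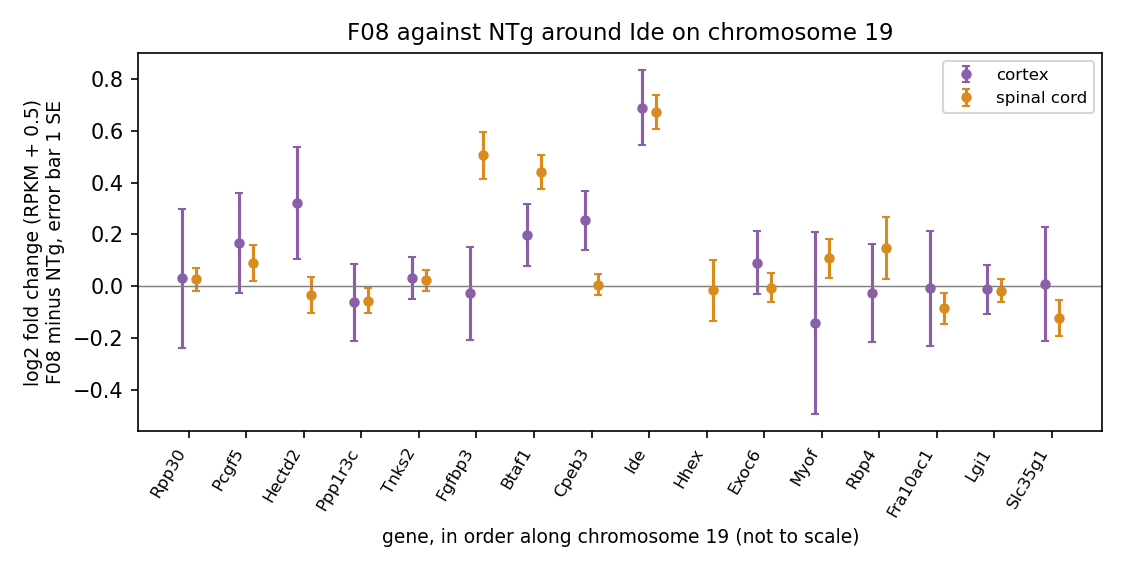
Log2 fold change of F08 against NTg with 1 SE for genes of chromosome 19 in order of position, 15 in cortex and 16 in spinal cord. Ide stands at 0.69 in cortex and 0.67 in spinal cord, and Cpeb3 at 0.26 and 0.01.

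Gene lists in the spinal cord of F08 mice moved by small amounts. Ribosomal protein genes (70 of 83 below 0, median -0.03, adjusted p = 6.34e-08) and oxidative phosphorylation genes (40 of 51, -0.02, 4.79e-06) were lower, both with adjusted p = 0.739 with an estimated correlation. Cox5a, a subunit of cytochrome oxidase, was 157 ± 5.69 against 173 ± 6.48 RPKM. Glucocorticoid response genes were lower (13 of 17, median -0.09, adjusted p = 7.01e-06; adjusted p = 0.487 with an estimated correlation), and 3 passed adjusted over the list alone (Sgk1, Per1 and Dusp1). Sgk1, a kinase induced by glucocorticoids, was 23.7 ± 6.36 against 43.3 ± 16.0 RPKM. Immediate early genes were lower by a median of -0.12 (14 of 20, adjusted p = 4.07e-04; adjusted p = 0.472 with an estimated correlation). These 4 lists were called in all 12 leave-outs, with glucocorticoid medians of -0.15 to -0.06, immediate early medians of -0.15 to -0.05 and ribosomal medians of -0.05 to -0.02. Cholesterol synthesis (13 of 21 below 0, median -0.04, adjusted p = 0.0122), blood (7 of 7, -0.27, 0.0183), choroid plexus and ependyma (9 of 11, -0.10, 0.0405) and skeletal muscle genes (4 of 4, -0.14, 0.0410) were lower as well. Motor neuron (12 of 15 above 0, median 0.09, adjusted p = 0.0410) and hippocampus and thalamus genes (14 of 16, 0.04, 0.0334) were higher. Dorsal root ganglion genes went the same way and did not pass (5 of 6 above 0, median 0.14, adjusted p = 0.123). With an estimated correlation adjusted p = 0.739 for cholesterol, choroid plexus and motor neuron genes, adjusted p = 0.766 for blood and adjusted p = 0.472 for muscle and hippocampus genes. Without NTg 6326 the 10 lists became 4, and without F112 6324 they became 6; motor neuron and muscle genes lost their calls in 7 leave-outs each, choroid plexus in 5, hippocampus in 4, blood in 3 and cholesterol in 2. Medians over leave-outs ranged from -0.47 to -0.04 (blood), -0.05 to -0.01 (cholesterol), -0.13 to -0.03 (choroid plexus), -0.16 to -0.09 (muscle), 0.04 to 0.10 (motor neuron) and 0.03 to 0.08 (hippocampus). The choroid plexus call ended with quantile normalization (adjusted p = 0.0903) and the GC correction (0.0717), muscle with the first (0.0697) and blood with the second (0.0843). Smaller differences were seen in Apcdd1 (0.24), Wfdc1 (0.30), Plekhf1 (-0.45), Apold1 (-0.48), Rps4l (-0.41), Gimap6 (-0.38) and Ndufa5 (-0.14), and none of these 7 passed.

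Between the lines in spinal cord, Ide, Fgfbp3 and Btaf1 were lower in F112 than in F08. Ide was 9.76 ± 0.63 RPKM in F112 and 15.7 ± 1.76 in F08 (log2 fold change -0.66, SE 0.067, limma adjusted p = 0.00105), Fgfbp3 1.19 ± 0.17 and 2.13 ± 0.33 (-0.63, adjusted p = 0.0358) and Btaf1 3.53 ± 0.24 and 4.99 ± 0.55 (-0.44, adjusted p = 0.0431). In F112 their levels lay near those of NTg, with log2 fold changes of 0.02, -0.13 and 0.00 between those groups. They were the 3 genes of 13839 that passed, and 1435 had an unadjusted p under 0.05. Ide passed in all 12 leave-outs. Btaf1 passed without NTg 6322 and in no other leave-out (adjusted p up to 0.117), and Fgfbp3 passed without NTg 6322 or F112 6317 and in no other (up to 0.123). The Btaf1 call also ended with median-of-ratios scaling (adjusted p = 0.0598) and quantile normalization (0.0726), and both calls ended with no filter, only the compared groups or Rn45s (0.0577 to 0.183). Others with small p were 4930413G21Rik (-0.69, adjusted p = 0.0582; 0.0129 to 0.0496 in the 5 settings and 1 leave-out where it passed), Hbq1a (-0.71), A330023F24Rik (0.18), Rpl22l1 (0.20), Gm10845 (0.19), Mthfs (0.30) and 2010107E04Rik (0.16).

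Oligodendrocyte precursor genes were lower in F112 than in F08 in spinal cord (11 of 13 below 0, median -0.12, camera adjusted p = 0.00655; adjusted p = 0.341 with an estimated correlation). Sox10 and Olig1, transcription factors of that lineage, passed adjusted over the list alone, with Sox10 at 35.5 ± 2.09 against 43.4 ± 1.18 RPKM. Synaptic genes were lower (20 of 25, median -0.07, adjusted p = 0.0212). Interferon response (17 of 23 above 0, median 0.04) and heat shock genes (15 of 20, 0.05) were higher, both at adjusted p = 0.00474, and 1 interferon gene, Psmb8, passed adjusted over the list alone. These 3 lists had adjusted p = 0.695 with an estimated correlation. Ribosomal protein genes had 48 of 83 members above 0 and a median of 0.01 (adjusted p = 0.00655; adjusted p = 0.777 with an estimated correlation). The heat shock call ended without F112 6325 (median -0.01, adjusted p = 0.848), the precursor call without F112 6317 (0.148) and the interferon call without F08 6320 (0.0602), while the synaptic and ribosomal calls ended in 3 and 4 leave-outs. Medians over leave-outs ranged from 0.02 to 0.09 (interferon) and -0.01 to 0.05 (ribosomal). With the GC correction the synaptic call ended (median -0.03, adjusted p = 0.0597), and the precursor median was -0.05 and the interferon median 0.07. The ribosomal median was 0.03 under each of the 3 scalings, and the heat shock median 0.08 with quantile normalization. The 5 lists became 2 without F112 6317, 10 without F112 6316, 8 without NTg 6326, F08 6319 or F112 6324, and 9 with either other scaling.

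**Figure D3:**
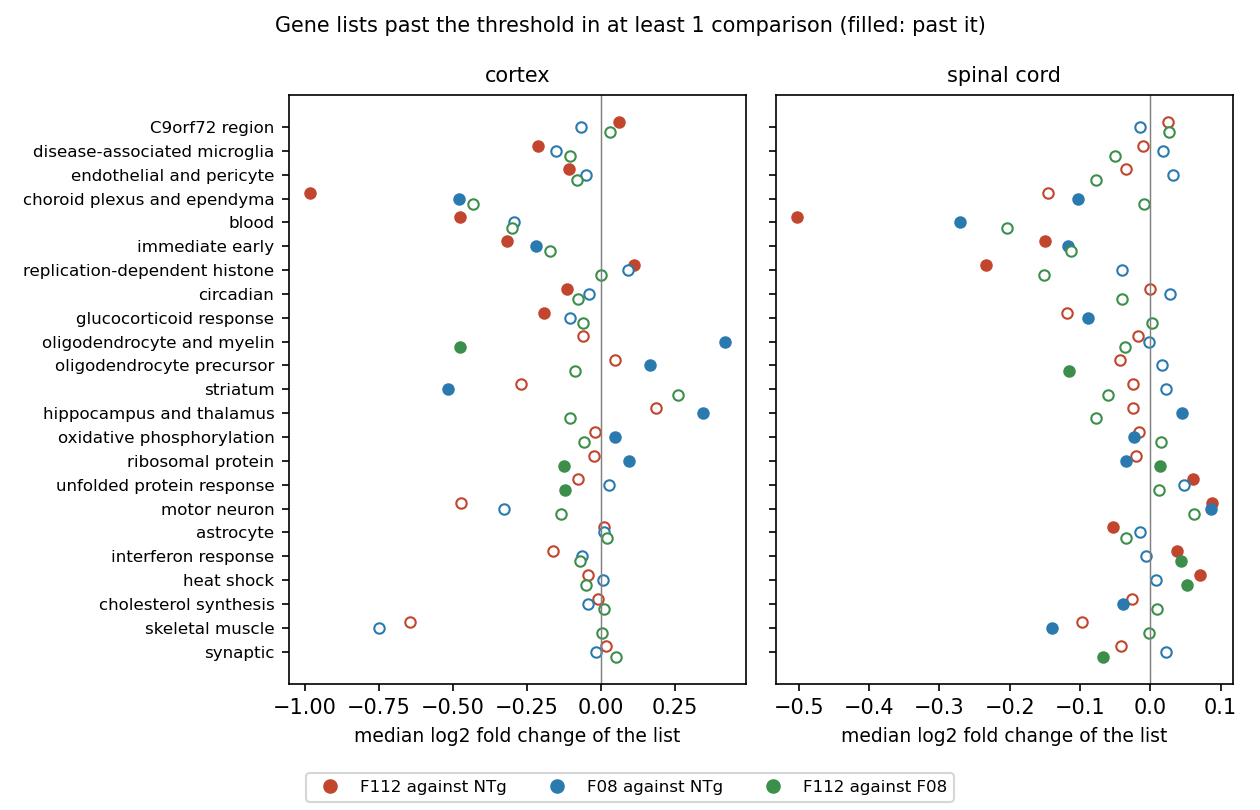
Median log2 fold change of the 23 gene lists called in at least 1 comparison, by tissue and comparison, with filled points for lists past the threshold and a different scale for each tissue. Choroid plexus genes in cortex F112 against NTg reach -0.98 (-0.15 without the 3 Ttr-rich libraries), and immediate early genes are below 0 in both tissues.

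The lists of ALS and FTD, autophagy and lysosome, RNA-binding protein and nucleocytoplasmic transport genes did not pass in any comparison. The C9orf72 region list passed in cortex F112 against NTg, as given above. Mouse C9orf72, also a member of the ALS and FTD list, passed over all genes tested there. In F112 against NTg the 30 ALS and FTD genes had medians of -0.04 in cortex (camera adjusted p = 0.893) and 0.01 in spinal cord (0.857). Autophagy and lysosome genes had -0.01 (adjusted p = 0.893) and 0.00 (0.859), RNA-binding protein genes -0.02 (0.590) and 0.01 (0.618), and nucleocytoplasmic transport genes -0.04 (0.373) and 0.02 (0.137). Tardbp, which encodes TDP-43, was 15.7 ± 1.93 RPKM in F112 cortex (n = 3) against 17.2 ± 1.62 in NTg (n = 4), and 23.7 ± 0.86 against 23.2 ± 0.33 in spinal cord (n = 4 each). Sqstm1, the autophagy receptor p62, was 140 ± 6.04 against 144 ± 9.46 RPKM in cortex and 190 ± 7.43 against 199 ± 8.82 in spinal cord. In the 6 comparisons, in order, 7, 8, 8, 9, 8 and 8 lists had a median, a mean and a test direction that differed in sign, and 0 of these were called.

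Mouse C9orf72 was the gene whose difference differed between the tissues. For F112 against NTg the cortex difference exceeded that of spinal cord by 1.37 on the log2 scale (SE 0.124, limma adjusted p = 3.12e-06). With the animal as a replicate block the limma adjusted p was 0.00189. The fit without the block used 1 spread per gene for both tissues. Its SE lies below that of the cortex difference alone (0.129), so its p may be too small. For F08 against NTg the excess was 0.89 (SE 0.119, adjusted p = 0.00297), which did not pass with the replicate block (adjusted p = 0.0976). It was the 1 gene of 13078 in each of these tests, with 468 and 383 genes at an unadjusted p under 0.05. For F112 against F08, 0 genes passed by limma and 523 had an unadjusted p under 0.05 (0 and 429 with the block). Without cortex NTg 6326, 2 genes passed for F112 (with Tmem107), and without cortex NTg 6323, 3 passed for F08 (with Gstm7 and Nrip3).

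Fold changes of the 2 lines against NTg were correlated across genes, and the lines share their NTg libraries. Pearson's r was 0.52 in cortex (rho 0.447, covariance 0.0193) and 0.45 in spinal cord (rho 0.336, covariance 0.00290). Simulated groups with no change, sharing a simulated NTg group, gave a median r of 0.51 (95% range -0.40 to 0.91) and 0.54 (-0.25 to 0.91). Their median covariance was 0.0202 and 0.00275. These ranges of r are too wide to tell a shared effect from none. With the NTg libraries split so that each line had its own, the median r over 6 splits was 0.02 (-0.37 to 0.10) in cortex and 0.01 (-0.22 to 0.13) in spinal cord. Calls in common numbered 0 in either tissue. This decides nothing, since F08 had 0 calls in cortex and each line had 1 in spinal cord. Fold changes in cortex and spinal cord had an r of 0.04 (rho 0.00967) for F112 against NTg, 0.11 (0.0659) for F08 against NTg and 0.07 (0.0464) for F112 against F08 over 13078 genes. Over leave-outs these r ranged from -0.03 to 0.07, 0.07 to 0.11 and 0.02 to 0.10. The r between the lines ranged from 0.33 to 0.66 in cortex and 0.35 to 0.56 in spinal cord. Genes are not independent replicates, so no p is given for these 5 correlations. After removal of genotype means, the 2 tissues of a mouse had an r of -0.03 to 0.18 across genes (median 0.05, 11 mice), and 3 of the 11 matched best with themselves.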

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

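The tests on mouse C9orf72, the test of Cpeb3 and the count of 4930413G21Rik libraries were chosen only after the result was seen.

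Mouse C9orf72 differed between the tissues, by a log2 difference of 1.37 between cortex and spinal cord for F112 against NTg (limma adjusted p = 3.12e-06, and 0.00189 with the replicate block) and 0.89 for F08 against NTg (0.00297 and 0.0976). In each pair the first p comes from the fit that used 1 spread per gene for both tissues. A depth difference between cortex libraries is argued against, since the F112 log2 fold change was 1.48 with log2 alignments as a covariate. Human transgene reads counted on the mouse gene in the cortex table stay open: both transgenic lines were higher in cortex, the smaller log2 fold change being 0.86, and platform and alignment may differ between the tables. A rise of the mouse gene in cortex alone stays open too, and these explanations cannot be told apart from RPKM values.

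In the spinal cord of F08 mice Ide was higher than in NTg. In the main fit Btaf1 and Fgfbp3 passed only between F112 and F08, and had limma adjusted p = 0.0639 and 0.284 for F08 against NTg. For Btaf1 the log2 fold changes were of like size, 0.44 for F08 against NTg and -0.44 for F112 against F08 (SE 0.067 each). Its pass between the lines alone therefore does not mark a smaller difference from NTg. For Fgfbp3 they were 0.51 and -0.63 (SE 0.091 each). F08 mouse 6321 stood above the rest of its group for each: 18.4 RPKM against 14.7 to 14.9 for Ide, 5.81 against 4.69 to 4.73 for Btaf1 and 2.63 against 1.91 to 2.02 for Fgfbp3. A few deviating libraries are argued against for Ide, since 8 of 8 F08 libraries lay above the highest NTg library of their tissue. The call in spinal cord led to the choice of Ide, so only the cortex libraries add to it. These come from the same 4 mice (6318 to 6321) and are not separate animals. Mouse 6321 was the highest F08 mouse in cortex too. It had 12.2 RPKM of Ide against a mean of 8.22 in the other F08 mice, 4.46 against 3.61 of Btaf1 and 2.13 against 1.53 of Fgfbp3. A change of the whole segment was first tested in cortex, where Btaf1 and Fgfbp3 averaged 0.084 (SE 0.119), short of the bound of 0.2 by less than that error and so undecided alone. Cpeb3, which lies between Btaf1 and Ide, had 0.0053 in spinal cord (SE 0.040), which argues against an unbroken changed stretch, although its cortex value was 0.26 (SE 0.114). A change in these 3 genes that spares Cpeb3, through the line's insertion site, flanking strain sequence or regulation, may remain and was not tested.

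The value of 4930413G21Rik was lower in spinal cord of F112 mice, and NTg mouse 6322 stood apart within its group at 2.62 RPKM against 1.74 to 1.88. A GC-dependent yield difference is argued against, as the log2 fold change was -0.78 after the GC correction against -0.80 before. The difference did not rest on a few F112 libraries, as 4 of 4 lay below the lowest NTg library. The gene was chosen for its small p in these same libraries, so this count adds no separate support. Reads shared with Rbbp6 on the opposite strand, whose log2 fold change was 0.03 (SE 0.048), and an effect of the line or the repeat stay open and were not tested. The call itself was lost in 11 of 12 leave-outs.

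Single libraries far from the other 3 of their group were found in 18 of 276 gene and group pairs, where chance gives about 1 in 20, or 13.8. In cortex NTg mouse 6322 had 401 RPKM of Mbp (others 783 to 808) and 6.40 of Sox10 (9.71 to 10.3). Cortex NTg mouse 6323 had 6.90 RPKM of Gabrb1 (5.48 to 5.69) and 12.51 of Gm7120 (7.67 to 8.24), and 6326 had 1.65 of Fam161a (1.26 to 1.31). Spinal cord NTg mouse 6326 had 1194 RPKM of Snap25 (1063 to 1077) and 10.4 of Ide (9.30 to 9.43), and 6327 had 18.8 of Pfkfb3 (19.7 to 19.9). Among spinal cord F08 mice, 6321 had 6.29 RPKM of Gabrb1 (6.87 to 6.97), 6320 had 0.692 of Hbq1a (1.02 to 1.06), and 6318 had 13.4 of Rps4l (15.9 to 16.1). Among spinal cord F112 mice, 6316 had 3.47 RPKM of Tmem107 (2.69 to 2.81), 6325 had 71.2 of Rpl22l1 (76.4 to 77.4), and 6324 had 39.0 of Hapln2 (44.0 to 44.6).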

How the results depend on the processing

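The settings with log2 alignments, with Rn45s, with the GC correction and without the 3 Ttr-rich cortex libraries were chosen only after the result was seen. Results that answer a comparison had 338 values under settings other than leave-outs. Of these, 289 were labelled the same, 26 weaker and 23 stronger. The same meant a count within 1.5 times, or a call kept in its direction. An uncalled fold change was the same if it stayed uncalled and moved by less than the gene's SD in the fit. A correlation was the same if it moved by less than its jackknife error over leave-outs. These last 2 rules allow a change of sign. The labels gave 0 as reversed, but a count has no direction and cannot be labelled so. Lists that turned direction therefore do not show in this 0. Of 4024 such values for single genes, 3935 stayed the same, 62 moved, 17 were weaker and 10 stronger. Of 129 values of called lists under the 3 scalings (43 each), 13 lost their call (3 with median-of-ratios, 4 with quantile, 6 with the GC correction), 10 medians moved over 1.5 times and 0 turned direction; no scaling moved the median of all genes by over 0.1. Testing entries of a symbol apart was not run, as no symbol recurred; 4930413G21Rik, Btaf1 and Fgfbp3 have no value at the 5 RPKM filter. Except where fewer genes or libraries were tested, the cause was not tested. The median SE was 0.16 in cortex and 0.056 in spinal cord. Depth, platform and the number of libraries differ between the tissues, and their parts in this were not separated.

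With an estimated correlation, 0 lists were called in each of the 6 comparisons. At 5 RPKM, lists numbered 5 in cortex F112 against NTg, 6 in cortex F112 against F08 and 6 in spinal cord F08 against NTg. With log2 alignments, and with Xist added, 4 lists were called in cortex F112 against NTg. With Rn45s there were 5 in cortex and 3 in spinal cord F112 against F08. In spinal cord F112 against F08 there were 9 with median-of-ratios or quantile scaling, 8 with Xist and 11 with the GC correction.

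Without the Ttr-rich libraries, cortex lists numbered 19 (F112 against NTg), 14 (F08 against NTg) and 6 (F112 against F08), 3 genes passed in F08 against NTg, and C9orf72 in F112 against NTg was 1.38 (not past the threshold). Both comparisons with NTg then kept only NTg 6323 and 6327, which had more alignments than the other NTg libraries. For cortex F08 against NTg, 1 gene passed with median-of-ratios scaling (C9orf72, 0.85) and 1 with the GC correction (C9orf72, 0.85).

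Genes in spinal cord F112 against NTg numbered 0 with pseudocount 1, no filter, 5 RPKM, only the compared groups, array weights, log2 alignments or Rn45s, and 5 with Xist and log2 alignments. For F08 against NTg there were 2 (Ide and Btaf1) with robust empirical Bayes, array weights, Xist or the GC correction, and 0 with log2 alignments. For F112 against F08 there was 1 (Ide) with no filter, 5 RPKM, only the compared groups or Rn45s, 6 with array weights or Xist, and 8 with Xist and log2 alignments. Tissue differences numbered 2 for F112 with no filter, and for F08 0 with the replicate block and 0 with Xist and log2 alignments.

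Leaving out each library gave these ranges. Genes passing ranged from 1 to 2 (cortex F112 against NTg), 0 to 1 (cortex F112 against F08), 0 to 2 (spinal cord F112 against NTg) and 1 to 4 (spinal cord F112 against F08). Lists ranged from 3 to 18, 4 to 14 and 3 to 9 in cortex (F112 against NTg, F08 against NTg, F112 against F08), and in spinal cord from 7 to 11, 4 to 10 and 2 to 10. Tissue differences ranged from 1 to 2 for F112 and 1 to 3 for F08 against NTg. C9orf72 in cortex ranged from 1.39 to 1.53, 0.80 to 0.95 and 0.51 to 0.64.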

Other observations

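The value with log2 alignments as a covariate and the look at Lrrc17 were chosen only after the result was seen.

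The single markers Aif1, Snap25 and Mbp differed little between genotypes in spinal cord. Motor neuron, astrocyte and oligodendrocyte precursor lists were called there in some comparisons, as given above. Aif1, a marker of microglia and macrophages, was 2.61 ± 0.32 RPKM in F112, 2.63 ± 0.14 in F08 and 2.65 ± 0.44 in NTg (SD, n = 4 each). Snap25, a synaptic protein of neurons, was 1096 ± 45.8, 1069 ± 31.9 and 1102 ± 62.1 RPKM, and Mbp 4958 ± 147, 5161 ± 146 and 5180 ± 341 RPKM. In cortex Gfap was 48.5 ± 6.28 RPKM in F112 (n = 3), 50.9 ± 16.9 in F08 and 33.9 ± 8.85 in NTg (n = 4 each), and did not pass in either comparison with NTg. Slc17a7, a glutamate transporter of cortical neurons, was 256 ± 39.8, 231 ± 60.7 and 237 ± 35.8 RPKM in cortex. Pan-neuronal genes in F112 against NTg had medians of -0.01 in both tissues (camera adjusted p = 0.628 in cortex and 0.618 in spinal cord).

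Lrrc17, a secreted leucine-rich repeat protein, was at 143 to 1190 RPKM in the cortex libraries and at most 0.144 RPKM in spinal cord. No level is compared here between the tables, since platform and alignment can differ.

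The same libraries were split into groups of the same sizes in all 35 ways for each comparison, and each split was tested alike. The real grouping is 1 of the 35 and is included in each count here. For gene counts, 2 splits in cortex F112 against NTg gave at least the real count of 1 (highest other 2), 35 in F08 against NTg (real 0, highest other 271) and 35 in F112 against F08 (0 and 2). In spinal cord they were 3 (real 1, highest other 28), 4 (1 and 1) and 2 (3 and 3). For list counts they were 21 (real 9, highest other 19), 28 (8 and 18) and 35 (3 and 19) in cortex, and 14 (8 and 11), 8 (10 and 13) and 24 (5 and 13) in spinal cord. For tissue differences they were 9 (1 and 108), 6 (1 and 348) and 35 (0 and 122), and for the correlation of tissues 25 (0.04 and 0.29), 16 (0.11 and 0.32) and 23 (0.07 and 0.27). Chance cannot be excluded for 15 of the 18 results. For the 3 with a real count of 0 every split reaches that count, so this test decides nothing. The splits below that follow depth or Xist are counted among the 35.

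Several of these splits called many more genes than the genotypes did and point to a structure of the samples. The split with 271 genes set cortex NTg 6322 and 6326 and F08 6318 and 6319, which had the fewest alignments of the 8 libraries, against the other 4, and the same mice gave 348 tissue differences. The split with 108 grouped F112 6316 and 6317 with NTg 6322 and 6326, again the mice with the fewest cortex alignments, and that with 122 grouped 6316 to 6319. The 28 genes in spinal cord came from setting the mice with high Xist (6316, 6317, 6322 and 6323) against the others, and the r of 0.29, 0.32 and 0.27 also came from setting mice with high Xist against the rest. Within mice of high and low Xist, 4930413G21Rik in spinal cord F112 against NTg was -0.84 and -0.77. With log2 alignments as a covariate, C9orf72 in cortex F112 against NTg was 1.48.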
